A study of Homo sapiens with 4 samples.

How the data were processed

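RNA sequencing libraries of MCF-7 cells were compared between a group transfected with scrambled siRNA and a group transfected with HOXB2 siRNA, with 2 libraries each, as the labels group them. Per the labels, the siRNA was delivered with a lipid reagent, the treatment lasted 24 h, and the cells were kept for 72 h in phenol red-free medium with charcoal-stripped serum. Libraries were made from poly(A)-enriched RNA. The deposited table held raw counts per Ensembl gene, 1 column per library, which the authors had not scaled. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.11b and featureCounts on GRCh38. The strand setting, the annotation release and the treatment of reads with several alignments are not given in the sources used here. The values were checked to be whole numbers, and no count column was left out.

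The table had 63140 genes. A table of gene names gave symbols for 42291 of them, GENCODE release 29 gave symbols for a further 16240, and 4609 had none. Positions came from GENCODE release 29 for 58126 genes, and transcript length and GC content were available for 58072. Gene counts per library ranged from 5218975 to 10997547. In simulated data with 2 libraries per group, edgeR recovered 15% of 2-fold changes and 80% of 4-fold changes among 200 changed genes. It called 4 unchanged genes. DESeq2 recovered 15% and 68%, and limma-voom 15% and 82%. Most 2-fold changes were thus missed in that simulation. The adjusted threshold depends on how many genes change, so that these shares need not hold for the data, where 2317 genes were called.

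Genes were filtered with filterByExpr by group, which left 14199, and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit and test on group alone). The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The SE was computed from the edgeR test statistic and the log2 fold change before shrinkage, while the log2 fold changes given are those edgeR reports after shrinkage. The SD of a group's CPM came from its 2 libraries. Gene lists, 45 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, with adjustment over the lists; camera with an estimated correlation and fry were run beside it. Each list count was also made with p-values adjusted over the list alone. In simulated data 1 of 100 random lists had a p under 0.05 by camera with the preset correlation, 0 with an estimated correlation and 6 by fry. The simulated genes varied independently, so that these rates do not cover lists whose members vary together. A planted list of 30 members, 20 of them raised 2-fold, had a p of 1.57e-16 by camera with the preset correlation. Its p was 0.0112 with an estimated correlation and 0.00482 by fry. Standing alone among 43 lists, neither of these latter values would pass after adjustment. The estimated correlation was 0.12 for cytoplasmic ribosomal proteins and 0.81 for keratins.

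The comparison, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took genes past the threshold with a mean of at least 5 CPM and no overlap between groups: the 10 largest increases, the 10 most negative changes, and the 4 most abundant others that changed at least 2-fold. It had 1361 eligible genes. HOXB2 was always named, and for each list described at most 4 members with the smallest adjusted p were named.

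The alternatives fixed at the same time were DESeq2 size factors, library size alone, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 2 libraries, the replicate number as a block, and leaving out each library in turn, where the lone library is assumed to vary like the others. Those chosen after the data were seen were an offset from a smooth trend (5 degrees of freedom) of log2 CPM on GC content and length in each library, that offset with the block, the subtraction of an even background estimated from olfactory receptor genes in proportion to exon length, both together, and thinning to the smallest total. With a GC trend planted in simulated data, 1319 unchanged genes were called without the offset and 6 with it. That trend was a straight line in GC content, equal in both replicates of a group and without a length term. It was therefore simpler than the trends in the libraries, which also separated replicates. With a planted background, 137 were called without subtraction and 14 with it. That background was planted evenly and its known density was subtracted, so that the estimate from olfactory receptor genes was not tested by simulation. Spearman correlations with GC content were taken over genes above 8 CPM. Intervals on counts are exact and cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Splits of the libraries were not used as a test, since 2 libraries per group give too few.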

Results

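Messenger RNA was profiled in MCF-7 cells, an estrogen receptor-positive line derived from human breast cancer, after transfection with a small interfering RNA (siRNA) against the homeobox transcription factor HOXB2 or with a scrambled control siRNA. Each group held 2 libraries, and the labels give 24 h of siRNA treatment and 72 h in medium with charcoal-stripped serum, which is depleted of steroid hormones. Gene counts summed to 10997547 and 9845554 in the scrambled siRNA libraries. They summed to 5218975 and 6419527 in the HOXB2 siRNA libraries, so that depth differed with the group. Nothing in the labels says that the replicates came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical. Across genes, log2 CPM (counts scaled to an equal library total) correlated at r = 0.973 between the scrambled siRNA libraries, at 0.969 between the HOXB2 siRNA libraries, and at 0.913 to 0.938 between groups. Genes are not independent replicates.

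HOXB2 itself (ENSG00000173917; GRCh38 chromosome 17, 48540894 to 48544989, minus strand, protein-coding) was measured first. It had 154 and 103 counts in the scrambled siRNA libraries and 36 and 20 in the HOXB2 siRNA libraries. The scaled levels were 13.8 and 9.43 CPM against 8.12 and 3.04 CPM, a mean of 11.6 ± 3.07 (SD, n = 2) against 5.58 ± 3.59 (SD, n = 2). Both HOXB2 siRNA libraries lay below both controls, with a log2 fold change of −1.10 ± 0.45 (SE), but the difference did not pass the threshold over all genes (edgeR, adjusted p = 0.0881). With an offset for GC content and transcript length the log2 fold change was −1.55 ± 0.38 (adjusted p = 0.0405), and without HOXB2 siRNA replicate 1 it was −1.88 ± 0.56 (adjusted p = 0.0230). Without HOXB2 siRNA replicate 2 it was −0.49 (adjusted p = 0.558), without scrambled siRNA replicate 1 it was −0.78 (adjusted p = 0.428), and the adjusted p over all alternatives ran from 6.85e-07 to 0.558. Of the 15 listed genes of the HOXB cluster, 7 were tested and none passed by edgeR, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. DESeq2 and limma-voom also called none. The log2 fold changes were −0.35 for the neighbouring gene HOXB3, 0.27 for HOXB4, −0.87 for HOXB6, −0.07 for HOXB7, 0.57 for HOXB9 and −0.06 for the antisense transcript HOXB-AS1. HOXB-AS1 (48543551 to 48551250, plus strand) overlaps the positions of HOXB2 and HOXB3. Because the strand setting of the counting is not given, reads from the overlaps cannot be told apart.

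Differential expression analysis by edgeR identified 2317 genes of 14199 tested, of which 1041 were higher and 1276 lower with HOXB2 siRNA. Changes of at least 2-fold accounted for 2060 of these genes, 854 higher and 1206 lower. The higher genes included the keratin gene KRT81 and the trefoil gene TFF3, and the lower genes included the matrix and growth factor genes CCN2 and IGFBP3. In 57.8% of the tested genes the libraries of the groups did not overlap, where chance gives 33.3%, and the median log2 fold change of all tested genes was −0.07. DESeq2 called 1299 genes, 816 higher and 483 lower, so that 62.8% of its calls were higher against 44.9% by edgeR. Scaling by library size alone moved the median to −0.25 and called 1092 genes. An offset for GC content and length gave 1281 genes and the subtraction of an even background gave 1198, of which 55.4% were higher. The offset left the tests a median of 6.79 prior degrees of freedom against 49.0 without it, so that a gene could end above the threshold at a nearly unchanged fold change. With the replicate number as a replicate block 5171 genes were called, and 4338 with the offset and the replicate block. The block leaves 1 residual degree of freedom, and its median prior degrees of freedom were infinite, so that nearly all of the spread assumed for a gene came from the other genes. Without scrambled siRNA replicate 1, scrambled siRNA replicate 2 and HOXB2 siRNA replicate 1 in turn, 1118, 725 and 865 genes were called.

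The 10 largest increases among the genes that met the naming rule ranged from 3.38 to 4.96 on the log2 scale. DACT3, a member of the family of Dishevelled-binding antagonists (GRCh38 chromosome 19, 46647612 to 46661138), went from 0.450 ± 0.249 to 14.6 ± 4.17 CPM (SD, n = 2 per group), a log2 fold change of 4.96 ± 0.56 (SE; adjusted p = 8.36e-09). Its few scrambled siRNA counts, 7 and 3, lay at the level of the estimated background. KRT81, a hair keratin (chromosome 12, 52285913 to 52291534), rose from 9.20 ± 3.82 to 216 ± 71.3 CPM, with a log2 fold change of 4.55 ± 0.37 (adjusted p = 3.11e-11). Its near-identical relatives KRT83 and KRT86 make the assignment of its reads uncertain. LIF-AS2, an antisense transcript whose reads cannot be told from those of its partner because the strand setting of the counting is not given in the sources used here, rose by 4.41 ± 0.54. CALML5, a calcium-binding protein of differentiating epidermis, rose by 3.98 ± 0.39, and TGM1, the transglutaminase that cross-links the cornified envelope, by 3.54 ± 0.45. TFF3, a secreted trefoil peptide (chromosome 21, 42311667 to 42315651), rose from 14.8 ± 2.32 to 169 ± 32.2 CPM, with a log2 fold change of 3.51 ± 0.33 (adjusted p = 7.90e-11). The transcription factor gene CREB3L1 rose by 3.69 ± 0.53, the exchange factor gene RASGRP2 by 3.68 ± 0.45, ASPHD1 by 3.48 ± 0.37 and the small GTPase gene RASD1 by 3.38 ± 0.40. The estimated even background amounted to 52.1% of the scrambled siRNA counts of CREB3L1 (15 and 4), 36.4% of those of RASGRP2, 19.9% for TGM1 and 11.5% for LIF-AS2, so that these fold changes depend on few control counts. With the GC and length offset these 10 log2 fold changes lay between 2.78 and 4.81, and each remained past the threshold.

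The 10 most negative changes ranged from −6.45 to −2.50. CCN2, the connective tissue growth factor gene (chromosome 6, 131948176 to 131951373), went from 9.94 ± 1.37 to 0.980 ± 0.527 CPM (SD, n = 2 per group), a log2 fold change of −3.40 ± 0.55 (SE; adjusted p = 1.88e-05). IGFBP3, which encodes a secreted binding protein for insulin-like growth factors (chromosome 7, 45912245 to 45921874), went from 471 ± 56.2 to 83.3 ± 15.4 CPM, a change of −2.50 ± 0.32 (adjusted p = 2.61e-07). CAV1, the main coat protein of caveolae, changed by −2.97 ± 0.47, and the interleukin 1 receptor gene IL1R1 by −3.18 ± 0.52. The Rho GTPase-activating protein gene DLC1 changed by −2.58 ± 0.51, AMOT, which encodes the junctional protein angiomotin, by −2.51 ± 0.48, the basement membrane gene FREM2 by −2.96 ± 0.49 and the carbonic anhydrase gene CA2 by −2.54 ± 0.36. TTN, a very long gene (chromosome 2, 178525989 to 178830802), had 568 counts over the scrambled siRNA libraries and 3 over the HOXB2 siRNA libraries, a depth-scaled ratio of 1.06% with an exact 95% interval of 0.218% to 3.11% that covers counting error only. An even background estimated from silent genes amounted to 51.4% of the scrambled siRNA counts of TTN and to 40.1% of those of DST, a cytoskeletal linker gene that changed by −2.51 ± 0.48. Under the offset for GC content and length the 10 log2 fold changes lay between −4.51 and −1.30, and DST no longer passed (−1.30 ± 0.39, adjusted p = 0.0707).

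**Figure D1:**
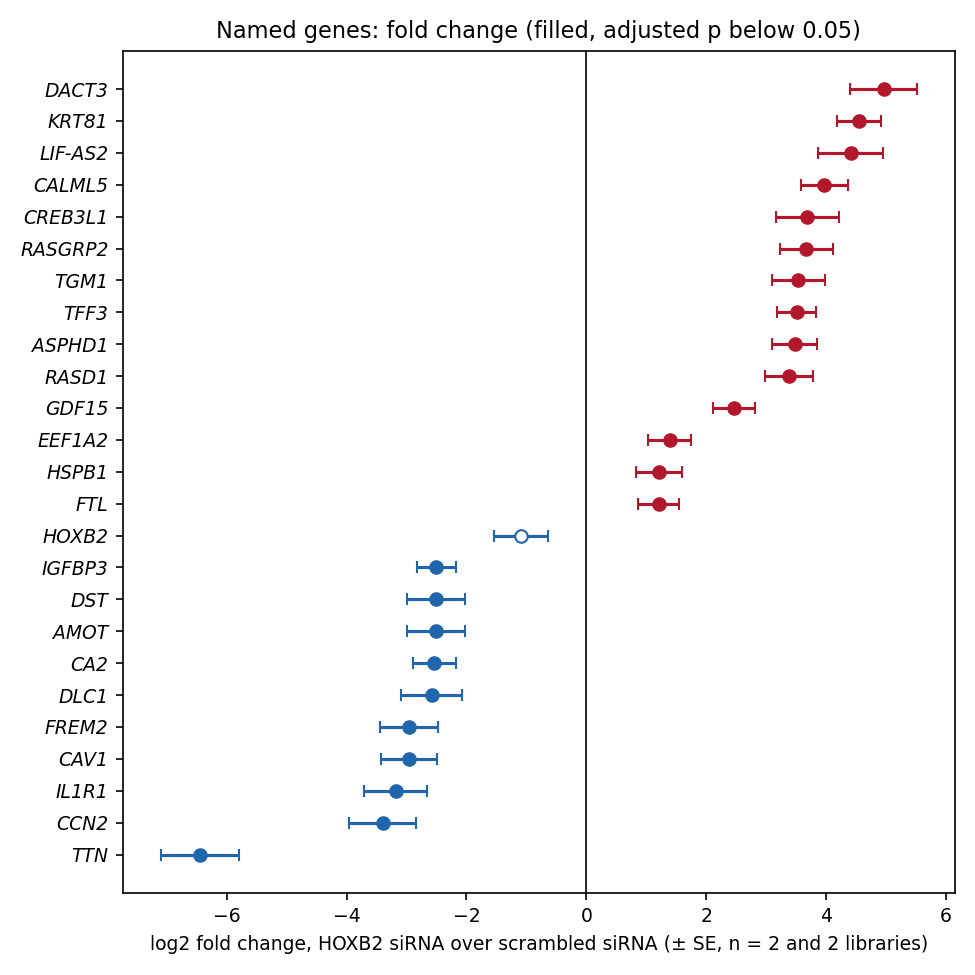
Log2 fold change of HOXB2 siRNA over scrambled siRNA (x axis) for HOXB2 and the 24 other genes named by rule (y axis), with bars for 1 SE from 2 libraries per group; red marks increases, blue decreases, and an open circle an adjusted p above 0.05. HOXB2 lies at −1.10, DACT3 at 4.96 and TTN at −6.45.

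Among the most abundant genes changed at least 2-fold, GDF15, a stress-induced member of the TGF-beta superfamily (chromosome 19, 18374731 to 18389176), rose from 499 ± 113 to 2756 ± 829 CPM (SD, n = 2 per group), a log2 fold change of 2.46 ± 0.36 (SE; adjusted p = 2.79e-06). The small heat shock protein gene HSPB1 went from 4989 ± 1152 to 11619 ± 5198 CPM, a change of 1.22 ± 0.39 (adjusted p = 0.0234). EEF1A2, a translation elongation factor gene with a close paralog, rose by 1.39 ± 0.36 (adjusted p = 0.00535) and FTL, the ferritin light chain gene, by 1.21 ± 0.35 (adjusted p = 0.0124). HSPB1 and FTL have pseudogenes, so that their counts and those of EEF1A2 depend on how shared reads were assigned. HSPB1 no longer passed with the GC and length offset (0.40 ± 0.22, adjusted p = 0.258), and HSPB1, EEF1A2 and FTL no longer passed without HOXB2 siRNA replicate 1 (adjusted p = 0.477, 0.235 and 0.172) or without scrambled siRNA replicate 2 (adjusted p = 0.410, 0.207 and 0.396). HSPB1 also did not pass without scrambled siRNA replicate 1 (adjusted p = 0.0726), with library size alone (adjusted p = 0.0682) or after background subtraction (adjusted p = 0.0959). FTL did not pass after background subtraction (adjusted p = 0.0587), and EEF1A2 did not pass after subtraction with the offset (adjusted p = 0.0722).

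Of 45 gene lists fixed before the data were examined, 43 had at least 5 tested members, and 9 passed the camera test with its preset correlation, 7 upward and 2 downward. With an estimated correlation none of the 9 passed, no list had an unadjusted p under 0.05, and the lowest adjusted p over all lists was 0.661. This loss cannot be read as the effect of correlation alone. The mitosis and G2/M list had an estimated correlation of −0.027, below the preset 0.01, yet its camera p went from 0.00145 to 0.0650. For the ATF4 list the estimate was 0.008, and the camera p went from 0.0201 to 0.141. For these 2 lists the estimates lay below the preset value, so that correlation cannot account for the higher p. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, of which the design left 2. In simulated data a planted list of 30 members, 20 of them raised 2-fold, had a p of 0.0112 by this test. Failing to pass it therefore says little about a list. The self-contained fry test also called none, with a lowest adjusted p of 0.135 and 11 lists at an unadjusted p under 0.05. By fry the planted list had a p of 0.00482. The mixed fry test, which asks whether members change in either direction, called 18 lists.

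Each list was also tested by camera at the preset correlation under 14 alternatives of scaling, filter, block, offset, background subtraction, thinning and left-out library. Among the 9 lists, cytoplasmic ribosomal proteins, immediate early genes and mitosis and G2/M passed under all 14, interferon-stimulated genes under 13, mitochondrially encoded mRNAs under 12 and nuclear genes of oxidative phosphorylation under 11. Keratins, mitochondrial ribosomal proteins and NF-kB genes passed under 9 each. Of the lists that did not pass at first, DNA replication and the HOXA, HOXC and HOXD clusters passed under 8 of 14, estradiol-lowered genes under 7, the small RNA pathway under 6 and the TGF-beta and BMP response under 4. The lysosome, endoplasmic reticulum chaperone and proteasome lists passed under 3, the ATF4 and luminal identity lists under 2, and the cholesterol synthesis and NRF2 lists under 1. Endothelial and fibroblast markers passed under 4 and 1 of the 11 alternatives with enough members. Nuclear noncoding RNAs passed under 1, upward, where the first test pointed downward (adjusted p = 0.937). With an estimated correlation no list passed under the GC and length offset (lowest adjusted p = 0.559), after background subtraction (0.774) or with both (0.668), and the other alternatives were not repeated that way.

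Interferon-stimulated genes were among the lists that moved upward. Of 29 tested members 11 rose and none fell over all genes, and 11 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.45 (camera, adjusted p = 1.90e-04; adjusted p = 0.661 with an estimated correlation). BST2, which encodes the antiviral membrane protein tetherin, rose from 27.3 ± 7.62 to 153 ± 57.8 CPM (SD, n = 2 per group), by 2.49 ± 0.33 on the log2 scale. IFI27 rose by 2.08 ± 0.32, the ubiquitin-like modifier gene ISG15 by 2.14 ± 0.34 and the exonuclease gene ISG20 by 1.60 ± 0.32. The list no longer passed without HOXB2 siRNA replicate 1 (median 0.09, adjusted p = 0.0902). Without HOXB2 siRNA replicate 2 the median was also 0.09, but the list passed (adjusted p = 0.00198), and 37 members were tested in each of these fits. Its median with the GC and length offset was 0.24 (adjusted p = 3.78e-05; adjusted p = 0.559 with the offset and an estimated correlation). NF-kB and inflammatory genes had a median of 0.49 (adjusted p = 0.0128; adjusted p = 0.661 with an estimated correlation), with 5 of 19 members higher and 1 lower, and 6 and 1 adjusted over the list alone. Lymphotoxin beta (LTB) rose by 3.23 ± 0.43, RELB by 1.51 ± 0.34 and TNF by 2.19 ± 0.64, while the complement gene C3 fell by 1.87 ± 0.39. RELB (0.74 ± 0.21, adjusted p = 0.0606) and TNF (1.91 ± 0.58, adjusted p = 0.0685) did not pass with the GC and length offset. The NF-kB list did not pass with that offset (median 0.18, adjusted p = 0.153), without scrambled siRNA replicate 2 (adjusted p = 0.0777) or after thinning to the smallest total (median 0.22, adjusted p = 0.0774).

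Immediate early genes, the first to respond to growth factors and stress, had a median of 0.49 (camera, adjusted p = 0.00262; adjusted p = 0.661 with an estimated correlation). Of 30 tested members 7 rose and 2 fell, and 13 rose and 3 fell adjusted over the list alone. The phosphatase genes DUSP5 and DUSP4 rose by 2.73 ± 0.37 and 1.27 ± 0.30, JUND by 1.42 ± 0.32 and IER3 by 1.31 ± 0.31. Under the GC and length offset the change of JUND was 0.36 ± 0.16 (adjusted p = 0.189). Keratins had a mean log2 fold change of 1.13 and a median of 0.15 (adjusted p = 0.00176; adjusted p = 0.661 with an estimated correlation). The 4 of 12 tested keratins that rose, over all genes and adjusted over the list alone, were KRT81, KRT16 (3.66 ± 0.56), KRT17 (4.23 ± 0.95) and KRT10 (0.91 ± 0.30). Neither KRT16 nor KRT17 exceeded 10 CPM as a group mean (7.66 and 2.07 CPM with HOXB2 siRNA). The keratin list did not pass with the GC and length offset (median −0.24, adjusted p = 0.117) or without HOXB2 siRNA replicate 1 (median −0.31, adjusted p = 0.164). Its median was −0.06 with scaling by library size alone. KRT10 did not pass with the offset, at 0.74 ± 0.21 (adjusted p = 0.0579). Among basal and myoepithelial markers, of which 4 of 18 rose and 5 fell, the same numbers as adjusted over the list alone, KRT16, KRT17 and the oxytocin receptor gene OXTR (2.54 ± 0.51) were higher and CAV1 was lower (camera, adjusted p = 0.937).

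The 82 tested cytoplasmic ribosomal protein genes had a median of 0.43 (camera, adjusted p = 1.25e-05; adjusted p = 0.661 with an estimated correlation), but only RPL28 (1.15 ± 0.33) and RPS28 (0.98 ± 0.32) passed singly and none adjusted over the list alone. RPL26 (0.82 ± 0.30) and RPS21 (0.93 ± 0.34) had an adjusted p of 0.0508 and 0.0517 by edgeR. Nuclear genes of oxidative phosphorylation had a median of 0.27 over 77 members (adjusted p = 0.00663; adjusted p = 0.705 with an estimated correlation), with NDUFB10 (1.00 ± 0.30) and ATP5F1D (0.99 ± 0.32) higher over all genes and none adjusted over the list alone. Mitochondrial ribosomal protein genes had a median of 0.24 over 76 members (adjusted p = 0.0128; adjusted p = 0.661 with an estimated correlation), with MRPL41 (1.43 ± 0.33) and MRPS26 (1.10 ± 0.30) higher, also adjusted over the list alone. Under the GC and length offset, RPS28 (0.42 ± 0.18), NDUFB10 (0.48 ± 0.15), ATP5F1D (0.23 ± 0.18), MRPL41 (0.18 ± 0.17) and MRPS26 (0.34 ± 0.16) did not pass (adjusted p from 0.0812 to 0.536). The mitochondrial ribosomal list did not pass with the GC and length offset (adjusted p = 0.117), after background subtraction (adjusted p = 0.151) or without scrambled siRNA replicate 2 (adjusted p = 0.0777). The oxidative phosphorylation list did not pass after background subtraction (adjusted p = 0.112) or without scrambled siRNA replicate 2 (adjusted p = 0.190). The 13 mRNAs encoded in the mitochondrial genome had a median of −0.51 (adjusted p = 0.0236; adjusted p = 0.705 with an estimated correlation). Of them MT-CYB fell by 0.97 ± 0.33 and none passed adjusted over the list alone. Mitochondrially encoded transcripts made up 3.87% and 3.34% of counts in the scrambled siRNA libraries and 1.71% and 2.79% in the HOXB2 siRNA libraries, and the list did not pass without HOXB2 siRNA replicate 1 (adjusted p = 0.417) or scrambled siRNA replicate 1 (adjusted p = 0.315).

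Genes of mitosis moved downward as a list. Of 38 tested genes of mitosis and G2/M, 5 fell and none rose, over all genes and adjusted over the list alone, and the median was −0.56 (camera, adjusted p = 0.0104; adjusted p = 0.661 with an estimated correlation). Over the alternatives the median ran from −1.06, without HOXB2 siRNA replicate 2, to −0.42, after thinning, and it was −0.87 with the stricter filter and −0.93 without a filter. The proliferation marker MKI67 went from 20.1 ± 2.55 to 6.03 ± 2.31 CPM (SD, n = 2 per group), a change of −1.76 ± 0.41, and the spindle assembly gene TPX2 changed by −1.46 ± 0.42. The kinetochore gene CENPF fell by 3.26 ± 0.79, from a mean of 2.75 CPM, and ASPM by 1.49 ± 0.41. With the GC and length offset the list kept its direction and its call at the preset correlation (adjusted p = 0.0122; adjusted p = 0.559 with the offset and an estimated correlation), while MKI67 (−1.02 ± 0.33, adjusted p = 0.0844), CENPF (−2.50 ± 0.83, adjusted p = 0.0862) and ASPM (−0.59 ± 0.46, adjusted p = 0.436) did not pass singly. Of 42 genes of DNA replication and G1/S, 6 fell and none rose, over all genes and adjusted over the list alone (median −0.41, camera adjusted p = 0.0577). They included the dihydrofolate reductase gene DHFR (−1.47 ± 0.41), MCM10 (−3.19 ± 0.91), GINS4 (−1.86 ± 0.57) and GINS1 (−0.95 ± 0.30). This list passed with the GC and length offset (adjusted p = 0.0122; adjusted p = 0.559 with the offset and an estimated correlation). It also passed without scrambled siRNA replicate 1 (adjusted p = 0.00902) and without HOXB2 siRNA replicate 2 (adjusted p = 0.0427). It did not pass without scrambled siRNA replicate 2 (median −0.14, adjusted p = 0.313), without HOXB2 siRNA replicate 1 (median −0.32, adjusted p = 0.196), or with an estimated correlation over all libraries (adjusted p = 0.705). MCM10 (−2.86 ± 0.88), GINS4 (−1.65 ± 0.46) and GINS1 (−0.68 ± 0.24) did not pass singly with the offset (adjusted p = 0.0682, 0.0540 and 0.109).

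**Figure D2:**
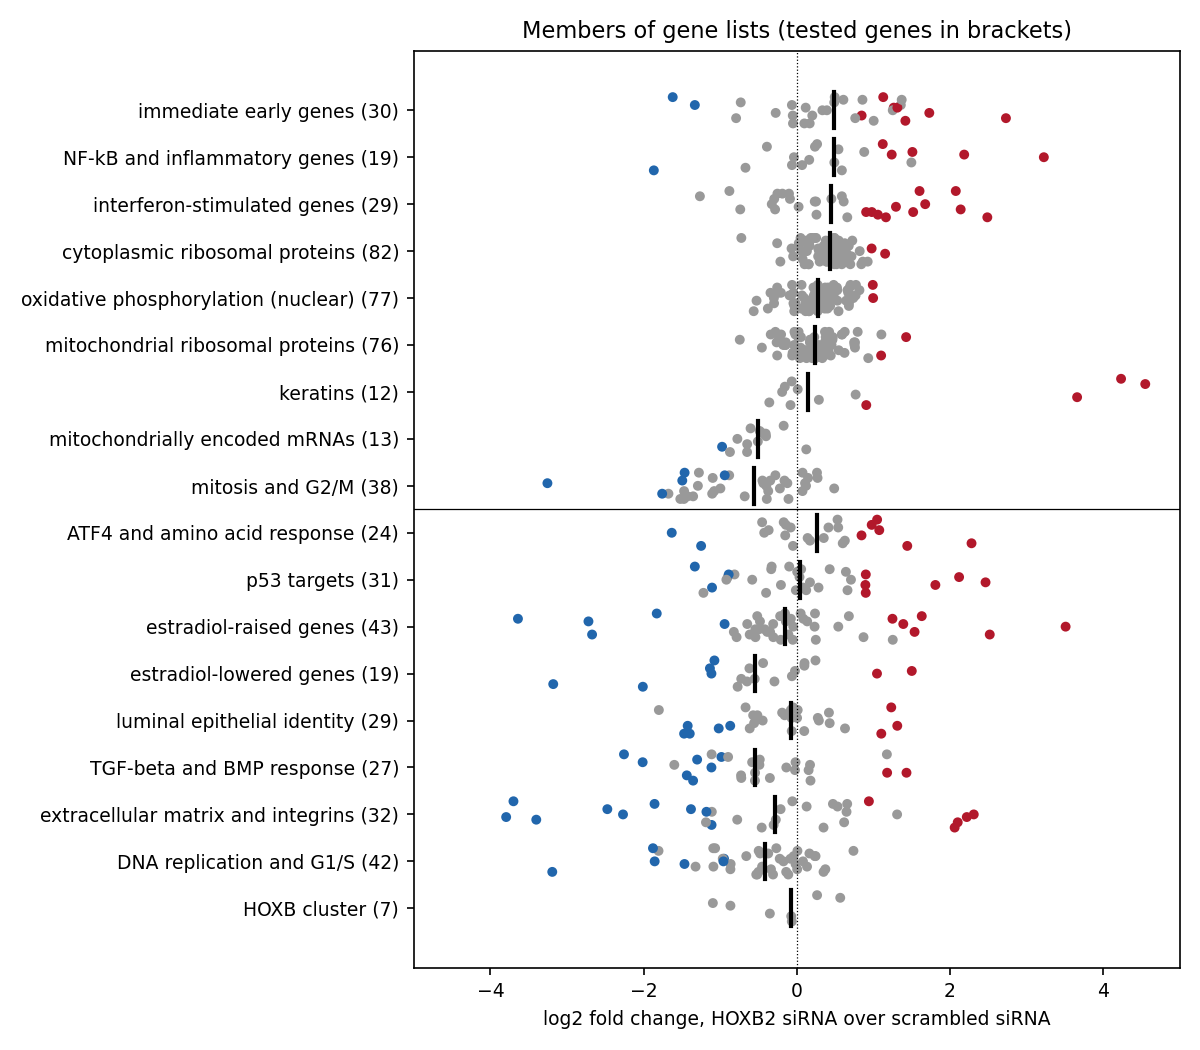
Log2 fold change of HOXB2 siRNA over scrambled siRNA (x axis) of each tested member of 18 gene lists (y axis, number tested in brackets); the 9 lists above the line passed the camera test with a preset correlation. Red and blue points are members higher and lower at an adjusted p under 0.05, grey points did not pass, vertical bars are list medians such as 0.45 for interferon-stimulated genes and −0.56 for mitosis and G2/M, and 2 extracellular matrix members lie beyond the axis.

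Estradiol-responsive genes did not move as 1 group in hormone-depleted medium. Of 43 tested estradiol-raised genes 6 rose and 5 fell, and 7 rose and 5 fell adjusted over the list alone. The median was −0.15 while the camera direction was upward (adjusted p = 0.680). TFF3, the trefoil gene TFF1 (1.63 ± 0.30) and the prostaglandin synthase gene PTGES (2.52 ± 0.37) were higher, and MYB was lower (−3.64 ± 0.86, from a mean of 2.44 CPM). Estradiol-lowered genes had a median of −0.55 (camera, adjusted p = 0.0577), with 2 of 19 higher and 5 lower, and 2 and 7 adjusted over the list alone. BCAS1 changed by −2.01 ± 0.31, IL1R1 by −3.18 ± 0.52 and ID2 by −1.11 ± 0.30, while CSTA rose from 61.5 ± 12.3 to 174 ± 50.4 CPM (SD). The list passed with the GC and length offset (adjusted p = 0.00732; adjusted p = 0.559 with the offset and an estimated correlation). It also passed with library size alone (adjusted p = 0.0320) and with the replicate block (adjusted p = 0.0251). It did not pass without any 1 library in turn (lowest adjusted p = 0.0759), or with an estimated correlation without the offset (adjusted p = 0.661). Among 29 luminal identity genes, 3 rose and 5 fell, the same numbers as adjusted over the list alone (median −0.08, adjusted p = 0.509). The estrogen receptor gene ESR1 went from 94.4 ± 19.3 to 35.8 ± 3.73 CPM (SD, n = 2 per group), a change of −1.40 ± 0.31, the E-cadherin gene CDH1 changed by −1.42 ± 0.31 and the androgen receptor gene AR by −1.47 ± 0.39, while SPDEF rose by 1.31 ± 0.30. ESR1 under the GC and length offset was at −0.88 (adjusted p = 0.0227). AR (−0.78 ± 0.27, adjusted p = 0.0979) and SPDEF (0.55 ± 0.16, adjusted p = 0.0590) did not pass with it. Of 12 targets of other steroid receptors 3 rose and 3 fell, and 3 rose and 4 fell adjusted over the list alone (adjusted p = 0.764), with HSD11B2 (2.19 ± 0.42) and PER1 (1.30 ± 0.30) higher and ERRFI1 (−1.84 ± 0.44) and KLF9 (−1.30 ± 0.35) lower. KLF9 did not pass with the offset (−0.90 ± 0.27, adjusted p = 0.0690).

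Genes of the extracellular matrix and integrins changed in both directions, with 5 of 32 higher and 11 lower, and 7 and 14 adjusted over the list alone (median −0.29; camera, adjusted p = 0.330). The matricellular gene CCN1 fell from 92.2 ± 1.24 to 16.6 ± 0.734 CPM (SD, n = 2 per group), a change of −2.47 ± 0.32, whereas TIMP1 rose by 2.10 ± 0.31 and the collagen VI genes COL6A2 and COL6A1 by 2.06 ± 0.31 and 2.22 ± 0.34. In the TGF-beta and BMP list 2 of 27 rose and 7 fell, and 2 and 9 adjusted over the list alone (median −0.55, adjusted p = 0.0577; adjusted p = 0.661 with an estimated correlation). The list passed with the replicate block (adjusted p = 0.0276), without scrambled siRNA replicate 2 (adjusted p = 0.0340), after background subtraction (adjusted p = 0.0423) and after thinning (adjusted p = 0.0248). Under the other 10 alternatives it did not pass, among them the GC and length offset (adjusted p = 0.117). BMP7 (1.43 ± 0.32) and PMEPA1 (1.18 ± 0.30) were higher, and the receptor gene TGFBR2 (−2.26 ± 0.52) and ID4 (−1.30 ± 0.34) were lower. ID4 did not pass with the GC and length offset (−1.25 ± 0.33, adjusted p = 0.0504). Of 13 genes of the epithelial-mesenchymal transition 3 rose and 3 fell, and 4 and 4 adjusted over the list alone (median 0.09, mean −0.03, adjusted p = 0.673). Fibronectin (FN1) changed by −1.89 ± 0.31 and TGFB2 by −2.40 ± 0.42, while TGFBI rose by 1.66 ± 0.33 and TGFB1 by 1.46 ± 0.30. Among 27 growth factor receptors and ligands 4 rose and 5 fell, and 4 and 9 adjusted over the list alone (adjusted p = 0.336). VEGFB (1.91 ± 0.31) and FGFR4 (2.00 ± 0.39) were higher, and FGFR2 (−2.01 ± 0.47) and IGFBP3 were lower. In the Notch list 4 of 22 rose and 3 fell, and 6 and 4 adjusted over the list alone (median 0.07, mean −0.10, adjusted p = 0.937). NOTCH2 (−1.65 ± 0.31), MAML2 (−2.58 ± 0.55) and the ligand gene JAG1 (−1.65 ± 0.44) were lower and NRARP (1.09 ± 0.31) was higher. With the GC and length offset JAG1 (−1.27 ± 0.36, adjusted p = 0.0595) and NRARP (0.17 ± 0.17, adjusted p = 0.560) did not pass.

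Of 24 genes of the ATF4 and amino acid response 6 rose and 2 fell, the same numbers as adjusted over the list alone (median 0.26; camera, adjusted p = 0.0577). The list passed without a filter (adjusted p = 0.0144) and with the replicate block (adjusted p = 0.0471). It did not pass under the other 12 alternatives or with an estimated correlation (adjusted p = 0.661). DDIT3, which encodes the stress transcription factor CHOP, rose from 13.5 ± 5.79 to 65.5 ± 13.2 CPM (SD, n = 2 per group), by 2.28 ± 0.34, NUPR1 rose by 1.44 ± 0.41 and CEBPB by 1.08 ± 0.30, and the amino acid transporter gene SLC38A2 fell by 1.63 ± 0.41. CEBPB did not pass with the GC and length offset (0.25 ± 0.16, adjusted p = 0.360). Of 31 p53 targets 6 rose and 3 fell, and 6 and 6 adjusted over the list alone (median 0.04, adjusted p = 0.336). GDF15, the pro-apoptotic gene BBC3 (1.81 ± 0.31) and the kinase gene PLK3 (2.12 ± 0.43) were higher and the antiproliferative gene BTG2 (−1.33 ± 0.32) was lower. In the endoplasmic reticulum chaperone list 3 of 22 rose and 1 fell, the same numbers as adjusted over the list alone (adjusted p = 0.320), with SDF2L1 (1.59 ± 0.36) and MANF (1.06 ± 0.31) higher and EDEM1 (−1.76 ± 0.36) lower. The SDF2L1 change with the GC and length offset was 0.66 ± 0.22 (adjusted p = 0.0945). The list passed with it (adjusted p = 0.0375; adjusted p = 0.559 with the offset and an estimated correlation), with it and the replicate block (adjusted p = 0.00855) and without a filter (adjusted p = 0.0323). Hypoxia and glycolysis genes numbered 3 higher and 2 lower of 36, and 3 and 3 adjusted over the list alone (adjusted p = 0.328), with ALDOC (2.30 ± 0.33) and ENO2 (1.26 ± 0.31) higher and PFKFB3 (−1.10 ± 0.30) lower. Of 29 lysosome and autophagy genes 4 rose, and 1 adjusted over the list alone (adjusted p = 0.0635), led by the transcription factor gene TFEB (1.44 ± 0.35). The lysosome list passed without a filter (adjusted p = 0.00129), without HOXB2 siRNA replicate 1 (adjusted p = 0.0269) and without scrambled siRNA replicate 2 (adjusted p = 0.0305). It did not pass without scrambled siRNA replicate 1 (adjusted p = 0.222), without HOXB2 siRNA replicate 2 (adjusted p = 0.0668), with library size alone (median −0.01, adjusted p = 0.106) or with an estimated correlation (adjusted p = 0.661). Of 24 genes of fatty acid synthesis and storage 3 rose and 1 fell, and 3 and 2 adjusted over the list alone (adjusted p = 0.432), with DGAT2 (1.99 ± 0.36) and SREBF1 (1.61 ± 0.32) higher.

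In the other HOX clusters 3 of 16 tested genes fell and none rose, over all genes and adjusted over the list alone (median −0.65; camera, adjusted p = 0.0641). They were the antisense transcript HOTAIR (−1.69 ± 0.41), HOXC13 (−0.89 ± 0.30) and HOXA1, with 1.86 and 0.453 CPM in the scrambled and HOXB2 siRNA groups. The list passed with the GC and length offset (median −0.85, adjusted p = 0.00229; adjusted p = 0.559 with the offset and an estimated correlation), where HOXA1 did not pass (−1.97 ± 0.62, adjusted p = 0.0736). It also passed without scrambled siRNA replicate 2 (adjusted p = 0.0340) and without HOXB2 siRNA replicate 1 (adjusted p = 0.0431). It did not pass without scrambled siRNA replicate 1 (adjusted p = 0.255), without HOXB2 siRNA replicate 2 (adjusted p = 0.213), or with an estimated correlation over all libraries (adjusted p = 0.661). Of 10 HOX cofactor genes, MEIS3 rose by 1.47 ± 0.30 and MEIS2 fell by 1.86 ± 0.56, and both passed adjusted over the list alone (adjusted p = 0.928 for the list), but MEIS2 did not pass with the GC and length offset (−1.43 ± 0.46, adjusted p = 0.0818). Among 5 tested neuronal markers ENO2 was higher and SYT1 and MAP2 were lower, over all genes and adjusted over the list alone (adjusted p = 0.640). MAP2 did not pass with the offset (−1.32 ± 0.36, adjusted p = 0.0548). The 3 tested structural RNAs without a poly(A) tail, RMRP (−3.11 ± 0.74), SNORD3A (−2.23 ± 0.73) and RN7SL1 (−1.41 ± 0.42), were lower, over all genes and adjusted over the list alone, and were too few for a list test. SNORD3A did not pass with the offset (−2.49 ± 0.68, adjusted p = 0.0524). Over all genes the counts of higher and lower members were 0 and 2 of 15 for the small RNA pathway, 0 and 2 of 6 for endothelial markers, 0 and 2 of 5 for fibroblast markers, 0 and 2 of 22 for Wnt targets and receptors, and 0 and 1 of 8 for the aryl hydrocarbon receptor response. They were 2 and 0 of 11 for the retinoic acid response, 2 and 0 of 20 for NRF2 and oxidative stress, 2 and 0 of 28 for replication-dependent histones, and 2 and 0 of 26 for apoptosis regulators. They were 1 and 0 of 25 for cholesterol synthesis, 1 and 0 of 36 for the proteasome, 0 and 1 of 6 for nuclear noncoding RNAs, and 1 and 0 of 3 for blood and immune cell markers. None of the 14 reference genes passed by edgeR, DESeq2 or limma-voom over all genes, or by edgeR adjusted over the list alone, with 1, 1 and 2 at an unadjusted p under 0.05. Adjusted over the list alone, these counts became 0 and 6 for the small RNA pathway, 1 and 2 for fibroblast markers, none for cholesterol synthesis, the proteasome and the histones, 1 and 0 for apoptosis regulators and 1 and 1 for blood and immune cell markers, and did not differ for the others.

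Library properties that moved with the group were measured beside these results. Over 8040 genes above 8 CPM, the log2 difference between groups correlated across genes with transcript GC content at Spearman's rho = 0.49 and with length at −0.38. Between replicates of the same group the correlation with GC content was 0.47 for scrambled siRNA and 0.75 for HOXB2 siRNA. The tenth of genes with the lowest GC content had a median difference of −0.31 between groups, and the tenth with the highest 0.70. Counts in 381 olfactory receptor genes, a family largely silent outside olfactory tissue, were 1305 and 899 in the scrambled siRNA libraries and 24 and 22 in the HOXB2 siRNA libraries, or 105 ± 19.3 against 4.01 ± 0.828 CPM of the unscaled total (SD, n = 2 per group). At an equal total, 25403 and 25588 genes had at least 1 count in the scrambled siRNA libraries and 19687 and 20300 in the HOXB2 siRNA libraries.

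**Figure D3:**
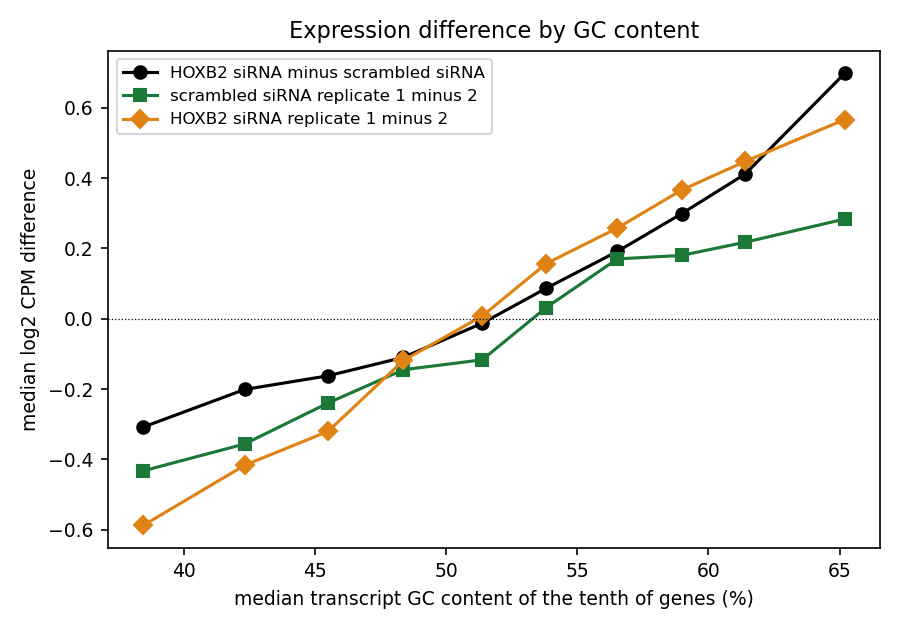
Median log2 CPM difference (y axis) in 10 bins of genes ordered by transcript GC content (x axis, median of the bin in %), between groups (black) and between replicates 1 and 2 of each group (green, scrambled siRNA; orange, HOXB2 siRNA). All 3 lines slope upward, from −0.31 to 0.70 for the difference between groups.

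**Figure D4:**
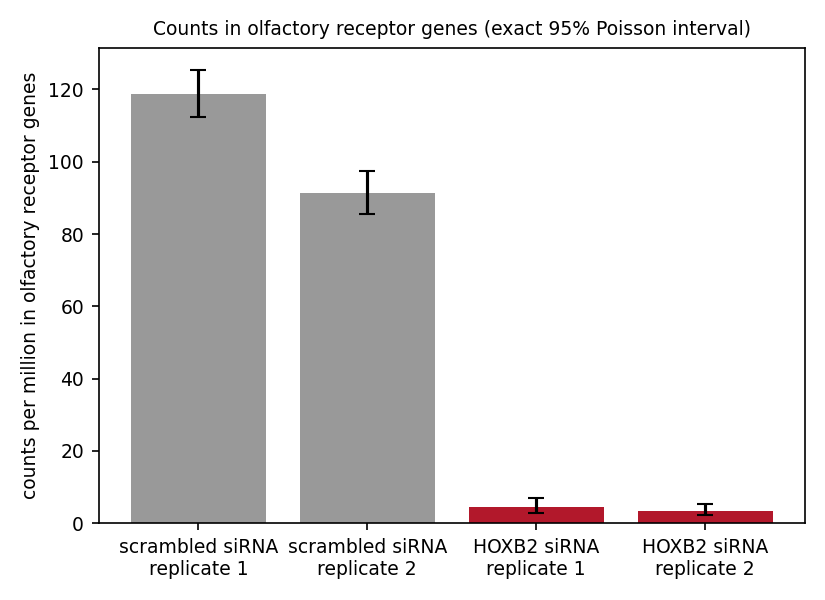
Counts in CPM of the unscaled total in 381 olfactory receptor genes (y axis) in each library (x axis; grey, scrambled siRNA; red, HOXB2 siRNA), with exact 95% Poisson intervals that cover counting error only. The scrambled siRNA libraries stand at 119 and 91.3 and the HOXB2 siRNA libraries at 4.60 and 3.43.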

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

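The offset for GC content and length, the background subtraction, their combinations and the thinning were chosen after the data were seen; the others were fixed before. Of the 24 named genes besides HOXB2, 20 kept their direction and stayed past the threshold under every alternative run, and HSPB1, EEF1A2, FTL and DST kept their direction but did not pass under at least 1. No named gene reversed.

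The count of changed genes was 1299 with DESeq2, 1092 with library size alone, 1281 with the GC and length offset, 1198 after background subtraction and 843 with both. The counts of higher genes were 390 with library size alone, 667 with the offset, 664 after subtraction and 468 with both. The counts of lower genes were 483 with DESeq2, 702 with library size alone, 614 with the offset, 534 after subtraction and 375 with both. Changes of at least 2-fold numbered 1203, 1027, 891, 1138 and 613 with DESeq2, library size alone, the offset, subtraction and both. The offset, the subtraction and both left fewer genes to test and lowered the median prior degrees of freedom from 49.0 to 6.79, 21.0 and 5.78; the parts were not separated. DESeq2 size factors in edgeR, limma-voom, both other filters and thinning gave counts within 1.5 times of 2317.

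Leaving out 1 library gave 725 to 2164 changed genes, 257 to 1125 higher, 468 to 1039 lower and 725 to 2113 changed at least 2-fold. The lowest counts were without scrambled siRNA replicate 2 and the highest without HOXB2 siRNA replicate 2, and these fits had 1 library fewer. The log2 fold change of HOXB2 ran from −1.88 to −0.49 over the same fits, and it was −1.55 with the GC and length offset, where it passed (adjusted p = 0.0405).

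With the replicate number as a replicate block, 5171 genes changed, 2439 higher and 2732 lower, and 2316 of the 2317 genes were among them. HOXB2 was then at −1.15 (adjusted p = 8.65e-04), but the test had 1 residual degree of freedom and an infinite median prior, so that its spread came from all genes. With the GC and length offset and the replicate block, 4338 genes changed, 2135 higher and 2203 lower, and HOXB2 was at −1.57. Deviations of libraries with the same number correlated across genes at r = 0.40, and at 0.25 with the offset (0.65 and 0.51 over genes above 8 CPM), but no label says that the numbers mark a shared day, and 2 pairs cannot show it.

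No list passed with an estimated correlation (0) or by fry (0). With an estimated correlation the 2 residual degrees of freedom limit what can pass. Without a filter 19 lists passed, and 14 with the replicate block. The cause of these higher counts was not tested. The keratin list reversed without a filter (median −2.18, adjusted p = 0.371), where keratins with few counts entered. Interferon-stimulated genes then had a median of −0.27 while their test stayed upward. The depth of the HOXB2 siRNA libraries limits what can be said of genes with few counts. HOXB1, HOXB5, HOXB8 and HOXB13 were not tested, with at most 9 counts in any library, the deeper scrambled siRNA libraries included.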

Other observations

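The interferon list tests without the offset were fixed before the data were examined. The predictions on the share held by 10 olfactory receptor genes and on the RNA sensor genes were written before their values were seen. All other tests in this part were chosen after the results were seen.

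The lower genes CCN2, CCN1, IGFBP3, CRIM1 and TGFB2 prompted the hypothesis that targets of the transcriptional coactivator YAP and its partner TEAD fall as a group. Of 22 listed targets 17 were tested, with a median log2 fold change of −1.25, 9 lower and 2 higher, but this count includes the genes that prompted the list. The 12 tested targets that did not prompt it had a median of −0.93, with 4 lower and 2 higher, and a camera p of 0.0597 (0.189 with an estimated correlation). That p was 0.0746 with the GC and length offset, 0.0215 after background subtraction and 0.0378 with both (0.201, 0.136 and 0.160 with an estimated correlation), so that a fall of YAP and TEAD targets may be real but is left open by these libraries.

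The higher genes KRT16, CALML5, TGM1, KLK6 and S100A14 prompted the hypothesis that epidermal differentiation genes rise as a group. The 13 tested members that did not prompt the list had a median of −0.36. The camera direction was downward, at a p of 0.415 (0.700 with an estimated correlation). Of them 2 were higher and 3 lower. With the GC and length offset the median of these 13 members was −0.43, with 0 higher and 3 lower. After background subtraction 12 were tested, with a median of −0.21, and with both corrections it was −0.35. In each of these last 2 settings 0 were higher and 1 lower. The camera direction stayed downward under every correction. A rise of the group was therefore not seen beyond the genes that prompted it, with or without the corrections. The downward tests did not pass either, so that a rise is not excluded.

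GC-rich and short genes were higher in the HOXB2 siRNA libraries. The trend with GC content also separated replicates within each group, with a smaller correlation across genes of 0.472, as library GC bias would give. The correlation with length was −0.43 between scrambled siRNA replicates but only −0.16 between HOXB2 siRNA replicates, against −0.38 between groups. The length part was therefore weak within the HOXB2 siRNA group. As the whole cause of the called changes, GC and length bias is argued against by the offset. Under it 38.8% of the called genes that could be tested stayed called with their sign. The 1399 calls that ended had a median absolute log2 fold change of 1.51 (median SE 0.45) before and 0.93 (median SE 0.36) after. The tests also lost prior degrees of freedom, from a median of 49.0 to 6.79 over all tested genes, so that calls can have ended from smaller folds or from a weaker test, which were not separated. With the offset and the replicate block, where the prior degrees of freedom were 957, 1799 of these 2286 genes were called. A response to HOXB2 siRNA that itself follows GC content was not tested.

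Silent gene families held counts in the scrambled siRNA libraries. Depth is argued against, since after thinning the lowest scrambled siRNA library still had 5103 more genes with a count than the highest HOXB2 siRNA library, and so are a few transcribed genes, since the 10 highest olfactory receptor genes held 8.03% of the family's counts. Counts per exon kilobase in other silent families were 1.33 and 1.27 times those in olfactory receptor genes in the scrambled siRNA libraries, which is consistent with an even background such as genomic DNA. In the HOXB2 siRNA libraries they were 6.63 and 6.27 times, from only 30 and 26 counts against 24 and 22 in olfactory receptor genes. These few counts were therefore not evenly spread over the silent families. An even background is argued against as the whole cause of the lower calls, of which 531 of 1276 (41.6%) stayed lower after subtraction. Another 352 could no longer be tested. With subtraction and the GC and length offset together, 233 of the 1276 stayed lower, at a median of 5.78 prior degrees of freedom. Both biases together as the whole cause are left open, and an uneven background was not tested. The background may have inflated other lower calls, since in 224 of the 1276 lower genes it made up over 50% of the scrambled siRNA counts.

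Interferon-stimulated genes were higher with HOXB2 siRNA. GC and length bias as the cause is argued against by the offset, under which the list stayed past the threshold (adjusted p = 3.78e-05; adjusted p = 0.559 with an estimated correlation) with 8 members higher and 0 lower, though its median went from 0.45 to 0.24. Without the offset the list did not pass with an estimated correlation (adjusted p = 0.661) or without HOXB2 siRNA replicate 1 (adjusted p = 0.0902). Sensing of this siRNA duplex cannot be told apart from loss of HOXB2 without a further HOXB2 siRNA. The control cells also received an siRNA, so that sensing common to both duplexes would be shared by the groups. The tested sensor genes IFIH1 (−0.25, adjusted p = 0.755) and EIF2AK2 (−0.68, adjusted p = 0.277) had a median of −0.46, and sensing need not raise them. RIGI (at most 4 counts) and TLR3 (at most 13) had too few counts in any library to be tested.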
